A study of Drosophila melanogaster with 3 samples.

How the data were processed

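ChIP-seq was done by the authors with an antibody against GFP on 3 biological replicates of mixed-sex Drosophila melanogaster embryos (0 to 16 hours) that express az2 with a C-terminal GFP. Per the labels the chromatin was sheared by sonication to fragments of 200 to 800 bp. The 3 replicates form 1 group. The 10 deposited peak lists, 5 for each of the builds dm6 and dm3, are 3 relaxed lists of single replicates (peaks plus background, meant as input to the irreproducible discovery rate), 1 relaxed list from pooled reads and 1 list thresholded by the irreproducible discovery rate (IDR). Per the labels the lists were called against a control alignment, which was not used here. The peak caller, its version and the IDR threshold are not stated.

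Each deposited list gives for every peak a signal value in column 7, which was never negative and was taken here as an enrichment score on a linear scale, since the caller is not stated. Column 9 of the deposited lists is the −log10 of the q-value, which ran from 3.59 to 4.06 in the dm6 IDR list and was not used to rank peaks. The deposited column 10 holds the summit as an offset in bp from the start of the peak, an other kind of value that places each peak at a single base. Column 8 held no p-values. In dm6 2 of the replicate lists ended at exactly 30000 peaks, so their length is not a count of binding sites. Peak lists hold no read counts, so the depth per sample is unknown here and no interval for depth was computed; intervals of shares are exact binomial (Clopper-Pearson) 95% intervals over peaks or genes, except for Wilson intervals in the plot of the gene lists, and intervals of odds ratios are conditional exact intervals. They cover counting error only, not differences between embryos or lines.

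The main analyses used the dm6 lists, the dm6 genome and the Ensembl annotation BDGP6.54, on the arms 2L, 2R, 3L, 3R, 4 and X. Coordinates are given from 1. Coordinates of dm3 were never converted to dm6, and the dm3 lists served only for list sizes and as an alternative. Replicate lists were compared after each was reduced to its 5786 peaks of highest signal, the number of IDR peaks, and peaks counted as shared at 1 bp of overlap. Chance levels came from 1000 random placements on the same chromosome with the peak length kept. An IDR peak counted as covered when its summit lay in a peak of the reduced list. A gene counted as promoter-bound when a summit lay within 500 bp of any of its TSSs. The 27 gene lists were compared with all other genes of the same class by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05. X and autosomes, and divergent and lone promoters, were compared by two-sided Fisher's exact tests. For 32 fixed motifs the windows of 100 bp to either side of each summit were compared with 5 control windows per summit, matched for arm, for lying near or beyond a TSS, for the offset to an unbound TSS and for GC class; mean GC content was 34.6% at summits and 34.8% in controls. Words of 8 bases were ranked on 2072 summits of 2L and 2R, and the best 20 were tested on the 3714 summits of the other arms.

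The genes named were set by rule: az2; the 25 IDR peaks of highest signal within 500 bp of a TSS and covered in all 3 replicates, by the gene of the nearest TSS and its divergent partner; the 3 members of each list with the highest promoter peak, or every bound member of lists of 10 or fewer; and the 5 highest peaks with no TSS within 2000 bp. Signal values after gene names are those of the promoter peak. Single genes had no test of their own.

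With 1 group of 3 replicates there was no contrast between groups, no regrouping of samples and no pairing. The alternatives covered the signal threshold, the overlap rule, list length, the TSS window, the TSSs used, covariates, control windows, word length, the build, and each replicate left out in turn by keeping the peaks covered in both others. Gene activity, chromatin accessibility and background of the GFP antibody were not analysed here. A single Polycomb group name did not match the annotation and was left out, and a symbol pattern took 4 Acp genes into the cuticle list and lbm stood among the architectural genes by mistake; these 5 were kept as listed, and the calls without them are among the alternatives.

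The methods were tested on simulated data. Over 50 runs the same gene lists were raised to an odds ratio of 4, and 250 of 300 tests of raised lists (83.3%) gave a call. There were 6 false calls in 850 tests of unchanged lists, and the median odds ratio was 4.03. Over 5 runs the logistic regression, with random covariates, called raised lists in 26 of 30 tests with 1 false call in 85. The CTCF core, planted in each of 5 runs, was called each time with 0 false calls in 155. A planted 8-mer was called in all 5 runs, with 1 false call among the 100 words kept. Those 100 include the planted word and any shifted copies of it, which could not count as false. Genes were bound independently of each other, and all windows were drawn at random from the genome. The false calls therefore do not cover genes that share a promoter or windows matched for GC content and TSS offset. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.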

Results

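The data were chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Drosophila melanogaster embryos 0 to 16 hours old, males and females mixed. The flies carried a transgene that makes the zinc finger protein az2 with green fluorescent protein (GFP) at its C-terminal end, and an antibody against GFP pulled down the chromatin. There was 1 group, with 3 biological replicates. Untagged embryos, a second protein or a second stage were not included, so no groups were compared. The question was where in the embryonic genome the tagged az2 protein was found. The processed data of the series are peak lists without read counts, from which the read depth of each replicate cannot be read. On the build dm6 the relaxed lists, which hold peaks together with background, had 30000 peaks in replicate 1, 22372 in replicate 2 and 30000 in replicate 3. The reads pooled over the 3 replicates gave 27145 peaks, of which the authors kept 5786 by the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks repeat between replicates. These 5786 peaks, with a median width of 430 bp and a signal from 133 to 4202, are the IDR peaks below. Ranges in parentheses after shares of peaks or genes are exact binomial 95% intervals, which cover counting error only.

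Among the highest peaks were several beside the start of genes. The peak upstream of CG14100 (FBgn0036889) had the highest signal of all, 4202, and ranked 1 in each of the 3 replicate lists; it covered 3L:19590396-19590843 in dm6, and its summit lay 97 bp from the transcription start site (TSS) in intergenic DNA. At px (FBgn0003175), a wing vein patterning gene with the head-to-head neighbour CG11362, the peak at 2R:22514075-22514518 had a signal of 3555 and its summit in an intron of px. At Ugalt (FBgn0024994), the carrier of UDP-galactose into the Golgi, the peak at X:2703674-2704107 had a signal of 3528. At Chro (FBgn0044324), a chromodomain protein of interbands and the mitotic spindle, the peak at 3L:22878681-22879127 reached 3089. Its summit lay 101 bp downstream of a Chro TSS, in the 5' untranslated region. The head-to-head neighbour of Chro was Ssl1, a subunit of the general factor TFIIH.

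By the rule fixed for naming peaks, the 25 highest peaks within 500 bp of a TSS that all 3 replicates covered had signals from 1856 to 4202 and stood no lower than rank 44 in any replicate list. Of these, 20 summits lay upstream and 5 downstream of the nearest TSS, at 14 to 480 bp. In 13 of the 25 the gene of the nearest TSS had a head-to-head partner within 500 bp upstream of its 5'-most TSS. At px, larp and gish the summit lay upstream of the nearest TSS but in an intron of the gene. That TSS was therefore not the 5'-most, and a promoter shared with the partner is not shown there. All but 1 of the 25 are named here. Genes of mitochondrial ribosomal proteins had 3 of them: mRpS10 (with the methyltransferase gene Art3) had a signal of 2932 at 3R:15229320-15229750, mRpS23 (with CenG1A) had 2829 at 2L:13835260-13835664, and mRpL41 had 2672 at 2R:15217559-15218016. Tcs5, of the complex that modifies tRNA with threonylcarbamoyl adenosine, shared a peak of 2767 with CHMP2B, a subunit of the membrane-cutting complex ESCRT-III. PNPase, the mitochondrial polynucleotide phosphorylase, had 2760, and ph-p, a subunit of Polycomb repressive complex 1, had 2454. Then came CG1888 (2424), CG8320 with the peroxisome gene Pex11ab (2263), CG9147 with the F-box gene Fbw5 (2170), Tina-1 (2120), and the RNA-binding protein gene larp with asRNA:CR46104 (2112). CG18549 (2109), CG31145 (2081), the prolyl isomerase gene Fkbp14 (2048), and the casein kinase gene gish with Mat89Ba (2036) followed. The last were PIG-G of glycolipid anchor synthesis with CG1602 (2019), RluA-1 (1921), tank with CG12194 (1879), the mitochondrial protease gene Lon with PIG-F (1871), and the noncoding gene lncRNA:CR31044 (1856). The PIG-G peak (2R:7518815-7519352) lay within 20 kb of the az2 gene.

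Some high peaks lay far from any TSS. The highest of those without a TSS within 2000 bp lay in intergenic DNA at 2R:13035131-13035562, 11902 bp from CG13323, with a signal of 3027 and rank 7 among all IDR peaks. The next lay in an intron of Tlk, a chromatin kinase gene (X:3742002-3742424, signal 1939), 3754 bp from CG31668 (2L:2202196-2202613, 1876), and 3339 bp from CycB, the gene of cyclin B (2R:22802762-22803157, 1807). The fifth lay in an intron of the nuclear receptor gene Hr3 (2R:10219868-10220294, 1676). All 3 replicates covered these 5 peaks. At the az2 gene itself (FBgn0025185, 2R:7510622-7512749) a peak at 2R:7512552-7512981 lay with its summit 18 bp from the TSS, with a signal of 187 and rank 3867. The flies carry a tagged copy of az2, and whether it adds to the signal here or at PIG-G cannot be told from the peak lists.

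The 3 replicates found largely the same peaks when each list was reduced to its 5786 peaks of highest signal. All 3 shared 4348 of them (75.1%, 74.0 to 76.3), whereas random placement on the same chromosomes gave a mean of 0.103% (1000 placements, one-sided permutation p = 0.001, the smallest they can give). Replicates 1 and 2 shared 81.3% (80.3 to 82.3), replicates 1 and 3 82.2% (81.2 to 83.1), and replicates 2 and 3 83.0% (82.0 to 83.9), against placed means of 3.12% to 3.28% (one-sided permutation p = 0.001 each). Across the 4302, 4325 and 4469 peaks with summits within 100 bp of each other the Spearman correlation of signal was 0.835, 0.833 and 0.868 for these pairs; it is across peaks, which are not independent replicates.

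Of the 5786 IDR peaks, 4198 (72.6%, 71.4 to 73.7) had their summit in a peak of all 3 reduced lists, 1142 in exactly 2, 427 in exactly 1, and 19 in none. The reduced lists are as long as the IDR list, so IDR peaks of low signal stand at their end by construction. In lists of 2 times that length all 3 replicates covered 5566 IDR peaks (96.2%), and in the whole relaxed lists 5683 (98.2%). The IDR peaks were exactly the 5786 pooled peaks of highest signal.

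Tagged az2 was found near promoters far more often than at random places. Of the 5786 summits, 2651 (45.8%, 44.5 to 47.1) lay within 500 bp of an annotated TSS, against 13.4% ± 0.442 (SD over 1000 placements) for random places on the same chromosomes, a ratio of 3.42 (one-sided permutation p = 0.001, the smallest they can give). The share was 58.3% (55.7 to 60.8) among the 1447 peaks of highest signal and 39.7% (37.2 to 42.3) among the 1447 of lowest. The summits near a TSS sat on its upstream side: 2230 of 2650 (84.2%) were upstream and 419 downstream, with a median offset of -109.5 bp (quartiles -204 and -43 bp).

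**Figure D1:**
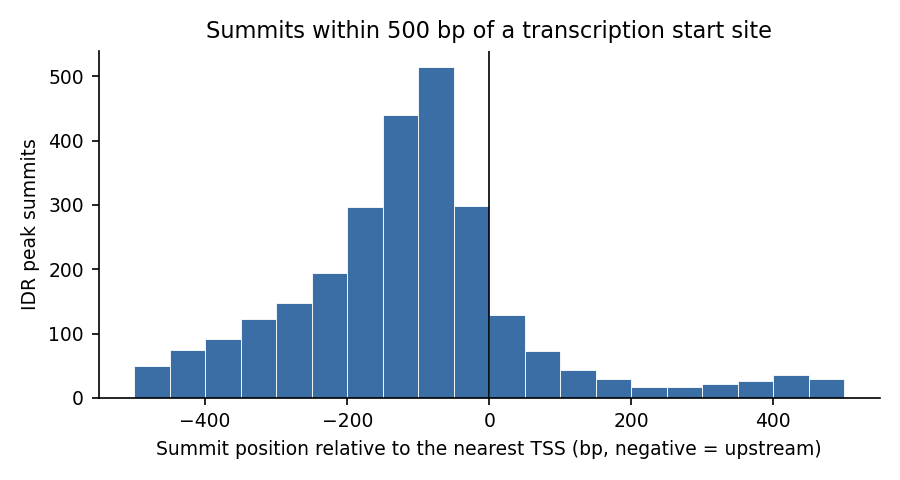
Number of IDR summits in 50 bp bins by offset from the nearest TSS (bp, negative upstream on the strand of the gene). The fullest bin lay 50 to 100 bp upstream and held 514 summits.

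Exons held few summits: 2.97% (2.55 to 3.44) lay in exons outside untranslated regions, 0.162 times the placed mean of 18.4%, and 1.42% in 3' untranslated regions, 0.286 times the placed mean. Intergenic DNA held 42.0% (1.37 times), introns 47.5% (1.11 times) and 5' untranslated regions 6.08% (1.81 times). Each of these 5 shares lay outside all 1000 placements (two-sided permutation p = 0.002 each, the smallest they can give). Of the summits beyond 500 bp from a TSS, 2097 (66.9%) lay in introns and 898 (28.6%) in intergenic DNA.

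The X chromosome was bound like the autosomes. On X, 427 of 2824 TSS regions (15.1%) held a summit, and on the autosomes 2193 of 14494 (15.1%), an odds ratio of 0.999 (0.891 to 1.12; two-sided Fisher's exact p = 1). Peak density was 44.6 per Mb on X, 46.1 on 2L, 39.1 on 2R, 44.7 on 3L and 43.5 on 3R. The small chromosome 4, which is rich in heterochromatin, had 22 peaks, or 16.5 per Mb. On it, 9 of 133 TSS regions (6.77%) were bound against 15.2% elsewhere, an odds ratio of 0.405 (0.181 to 0.796; two-sided Fisher's exact p = 0.00489), a test chosen after the densities were seen.

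A peak summit lay within 500 bp of a TSS in 3157 of 13945 protein-coding genes (22.6%, 21.9 to 23.3), called promoter-bound here. With the 2893 peaks of higher signal alone the count was 1891. Among other genes, 242 of 3261 long and other noncoding RNA genes (7.42%), 4 of 32 snRNA genes and 0 of 99 rRNA genes were promoter-bound.

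Ribosomal protein genes were bound more often than other genes. Of the 86 genes of cytosolic ribosomal proteins 59 (68.6%) were promoter-bound, against 22.4% of all other protein-coding genes, an odds ratio of 7.59 (4.73 to 12.5; two-sided Fisher's exact test, adjusted p = 1.53e-18 over 27 lists). Their highest peaks were at RpL7 (861, 2L:10200881-10201185), RpS27 (845, 3R:25247376-25247671) and RpL34b (799, 3R:9401153-9401520). Of 73 mitochondrial ribosomal protein genes 37 (50.7%) were bound, led by the 3 named above (odds ratio 3.54, 2.17 to 5.78; exact adjusted p = 1.02e-06). With only the 2893 peaks of higher signal the odds ratio of cytosolic ribosomal proteins was 4.66, and the mitochondrial call was lost (2.10). Without replicate 1 the mitochondrial odds ratio was 2.23.

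Aminoacyl-tRNA synthetase, cell cycle, glycolysis and spliceosome genes were also bound more often than other genes. Of 33 aminoacyl-tRNA synthetase genes, whose enzymes load tRNAs, 15 (45.5%) were bound, with IleRS (874), SerRS (674) and GluProRS (671) highest (odds ratio 2.86, 1.34 to 6.01; exact adjusted p = 0.0179). Of 48 cell cycle and replication genes 21 (43.8%) were bound (2.67, 1.43 to 4.91; exact adjusted p = 0.00636), among them CycE of the entry into S phase (598), Rbf2 of the retinoblastoma family (492) and dpa, a subunit of the replicative helicase (456). Of 13 glycolysis genes 8 (61.5%) were bound (5.48, 1.58 to 21.3; exact adjusted p = 0.0112), with Gapdh2 (1438), Ldh (920) and Eno (824) highest. Of 32 spliceosome genes 13 (40.6%) were bound (2.34, 1.06 to 5.01; exact adjusted p = 0.0491), with U2af50 (683), Sf3b6 (494) and snRNP-U1-C (438) highest. The synthetase call was lost without replicate 1 (odds ratio 2.44) and without replicate 2 (2.43), and the cell cycle call (1.94, 2.13 and 1.80) and the spliceosome call (1.67, 2.23 and 1.70) without replicate 1, 2 or 3. With the 2893 peaks of higher signal the synthetase (1.42), cell cycle (1.28) and spliceosome (2.13) calls were lost too. With only the peaks covered in all 3 replicates the cell cycle (1.55) and spliceosome (1.82) calls were lost, and the spliceosome call also with a 1000 bp window and with covariates for promoter structure and GC content (2.38). The glycolysis call was lost with the same covariates (3.00) and with only the 5'-most TSS of each gene (2.46).

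Genes of architectural proteins, which shape chromosome domains and insulate promoters, were bound in 13 of 29 cases (44.8%; odds ratio 2.78, 1.23 to 6.18; exact adjusted p = 0.0198). Their highest peaks were at Chro (3089), Cp190 (1210), a partner of several insulator proteins, and M1BP (629). The call was lost without replicate 2 (odds ratio 2.60), with the covariates (2.55) and with the 2893 peaks of higher signal (2.03).

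Genes of adult sensing and of the cuticle were nearly free of promoter peaks. None of the 180 chemosensory receptor genes was bound (upper bound of the odds ratio 0.0696; two-sided Fisher's exact test, adjusted p = 2.47e-19) and none of the 122 cuticle protein genes (upper bound 0.104; exact adjusted p = 2.74e-13). Of 51 odorant-binding protein genes 2 (3.92%) were bound, Obp99b (487) and Obp83g (145), an odds ratio of 0.139 (0.0164 to 0.530; exact adjusted p = 0.00306). None of 21 antimicrobial peptide genes was bound (upper bound 0.655; exact adjusted p = 0.0198). The antimicrobial peptide call was lost in 8 of 10 alternatives, among them those without replicate 1, 2 or 3 (0 bound each time) and the 250 bp and 1000 bp windows. The odorant-binding call was lost with the 2893 peaks of higher signal alone, where the odds ratio was 0.127.

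**Figure D2:**
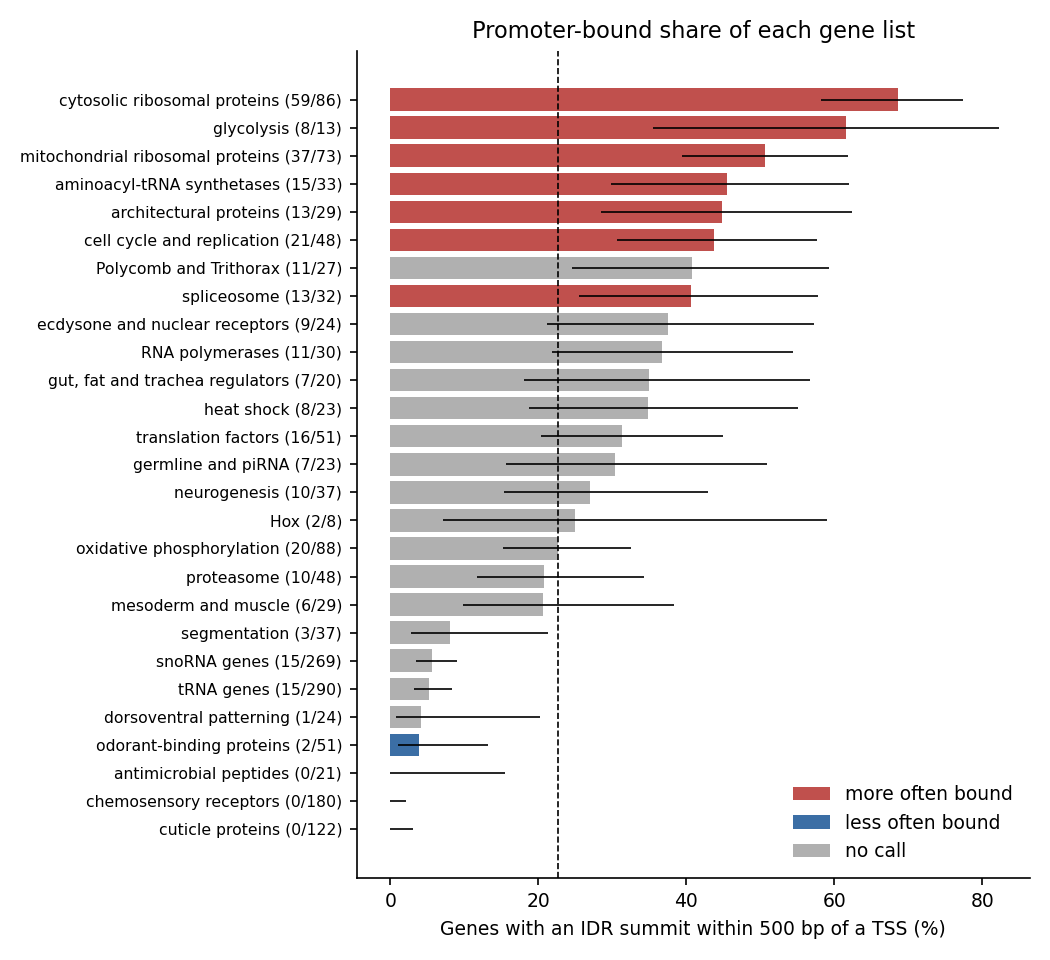
Share of genes with a summit within 500 bp of a TSS (percent, Wilson 95% intervals) in the 27 gene lists, with the lists called more often bound in red, less often in blue and not called in grey (the 3 lists with 0 bound genes, all called less often, show no bar). The dashed line marks the 22.6% of protein-coding genes, and cytosolic ribosomal proteins reached 68.6%; the tRNA and snoRNA lists were tested against other small and noncoding RNA genes, not against that line.

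Patterning and tissue genes did not pass the test as groups (16 lists in all, exact adjusted p from 0.0606 to 1), though single members had high peaks. Among segmentation genes 3 of 37 were bound, nkd of Wingless signalling (731), the anterior determinant bcd (518) and cnc (358). Of the 8 Hox genes Dfd (288) and Antp (164) were bound. Of 24 dorsoventral genes only cact, the inhibitor of Dorsal, was bound (853). Neurogenesis genes were bound in 10 of 37 cases, with the neuronal RNA-binding gene elav (1370) and the Notch targets E(spl)m3-HLH (979) and E(spl)m7-HLH (544) highest. Mesoderm and muscle genes were bound in 6 of 29, with sls (664), the heart regulator tin (566) and Tm1 (418) highest. Of 20 regulators of gut, fat and trachea 7 were bound, with the EGF receptor ligand spi (984), its antagonist aos (673) and Hnf4 (480) highest. Ecdysone and nuclear receptor genes were bound in 9 of 24, led by Hr96 (746), Eip75B (614) and Hnf4 again.

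Of 27 Polycomb and Trithorax genes 11 (40.7%) were bound, led by ph-p, the remodeller gene brm (1102) and E(z), a histone methyltransferase gene (798). The other lists not called were the proteasome (10 of 48; Rpn3 616, Rpn5 469, Rpn11 315), oxidative phosphorylation (20 of 88; Cyt-c-d 1138, ATPsynC 712, ND-ASHI 667), translation factors (16 of 51; eIF6 1582, eIF4EHP 1274, eIF3c 569) and RNA polymerases (11 of 30; Polr2B 807, Polr2H 646, Polr3E 592). Heat shock genes were bound in 8 of 23 cases (Hsp27 1414, Hsc70-5 578, Hsp26 490) and germline and piRNA genes in 7 of 23 (cuff 441, bgcn 380, piwi 365). Among RNA genes, 15 of 290 tRNA genes (tRNA:Tyr-GTA-1-8 1169, tRNA:Gln-TTG-2-1 516, tRNA:His-GTG-1-3 438) and 15 of 269 snoRNA genes (snoRNA:Psi28S-2949 564, snoRNA:Or-CD11a 548, snoRNA:Or-CD13 420) were bound. With a 1000 bp window the segmentation list passed as less often bound (odds ratio 0.252) and the snoRNA list as more often bound (1.95), and with a 250 bp window the RNA polymerases did (odds ratio 2.71). Counted by promoter region, an alternative added after seeing the data, the Polycomb and Trithorax (2.98) and RNA polymerase (2.77) lists passed as more often bound and the dorsoventral list (0.139) as less often bound.

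Promoters shared by head-to-head gene pairs were bound more often than promoters standing alone. Examples among the highest peaks are Chro with Ssl1, Art3 with mRpS10, and Lon with PIG-F. Of 3932 genes whose 5'-most TSS had an opposite-strand TSS of another gene within 500 bp upstream, 1671 (42.5%) were promoter-bound, against 1304 of 9320 genes (14.0%) with no other TSS within 500 bp. The odds ratio was 4.54 (4.16 to 4.96; two-sided Fisher's exact p = 2.43e-264). Counted per promoter region, 828 of 2099 divergent regions and 1114 of 9317 lone regions were bound, an odds ratio of 4.80 (4.30 to 5.35).

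Motif 7, the CTCF core and the ZIPIC core were more frequent within 100 bp of the summits than in control windows. Near a TSS these windows came from TSSs without a summit, so bound promoters were set against unbound ones. Values near a TSS can therefore also reflect which kinds of promoters are bound. Motif 7, a core promoter element of housekeeping genes, was found at 12.6% of the 5786 summits and 5.68% of 28930 control windows matched for TSS offset, arm and GC content (odds ratio 2.40, 2.19 to 2.64; two-sided Fisher's exact test, adjusted p = 1.83e-68 over 32 motifs). The core of the insulator protein CTCF was found at 1.21% against 0.235% (5.20, 3.66 to 7.38; exact adjusted p = 3.41e-19). The core of the zinc finger protein ZIPIC stood at 2.44% against 0.857% (2.89, 2.33 to 3.57; exact adjusted p = 1.67e-19), a call lost for summits beyond 500 bp from a TSS (odds ratio 1.34). For those summits the odds ratio of Motif 7 was 1.36. That of the CTCF core was 9.52 within 50 bp of the summit, and 2.23 against windows not matched for GC content. Some matches of Motif 7 (consensus CAKCNCTR) hold CACTG, a word counted below, so its count and that of the word overlap.

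In all, 12 of the 32 motifs were more frequent at the summits than in the controls, 6 were less frequent and 14 were not called. The other 9 of the 12 were the Mad and Brinker site (3.08% against 1.38%, odds ratio 2.26), the DRE palindrome (1.56), Motif 1 (1.51), the E-boxes CAGCTG (1.44) and CATATG (1.15), the GAGA element (1.42), the Su(Hw) core (1.22), the BEAF-32 site CGATA (1.08) and the Hunchback site (1.08). The less frequent ones were the Pho core (0.727), STAT (0.760), the Initiator (16.6% against 20.1%, 0.791), Caudal (0.838), Bicoid (0.852) and CCAAT (0.877). The DRE palindrome holds CGATA, so the counts of the DRE and the BEAF-32 site overlap. Direction was not stable for 6 of the 18 called motifs. Against windows 1000 bp away, which were not matched for GC content, the Mad and Brinker site (0.753) and GAGA (0.705) passed the test as less frequent at the summits. The other 4 had odds ratios below 1 that did not pass it: CAGCTG (0.917) against the same windows, the DRE (0.602) and the BEAF-32 site CGATA (0.898) at summits beyond 500 bp from a TSS, and the Su(Hw) core (0.950) at those within. Without replicate 1, 2 or 3 the Su(Hw) call was lost (1.19 to 1.22), without 1 or 2 the Hunchback call (1.07 each), and without 1 or 3 the BEAF-32 call (1.06 and 1.08). With the 2893 peaks of higher signal the DRE (1.09), Motif 1 (1.21), Su(Hw) (1.15), BEAF-32 (1.06), Hunchback (1.07), Bicoid (0.842) and CCAAT (0.912) calls were lost. Within 50 bp of the summit 9 calls were lost, among them CAGCTG (1.08) and STAT (0.867). For summits beyond 500 bp from a TSS the Initiator, Motif 1 and Hunchback calls were lost. The calls of Motif 7 and the CTCF core held in all 11 alternatives tried.

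Words of 8 bases chosen on 2L and 2R were then counted on the other arms. There, all 20 chosen words were more frequent at 3714 summits than at 18570 matched windows, with odds ratios from 3.01 to 9.67 (two-sided Fisher's exact tests, adjusted p at most 1.65e-13 over the 20). CACTGAGA was found at 4.50% against 0.485% (9.67, 7.42 to 12.7), CACTGTGC at 4.77% against 0.635% (7.82, 6.15 to 9.99) and CACAGTGG at 4.36% against 0.582% (7.80, 6.06 to 10.1). Of the 20 words, 15 held CACTG or its reverse complement CAGTG. The other 5 were GAGAGAAA, GATGGCGC, AGATGGCG, CAGGGGCG and ACTGAGAA. Only 4 of the 20 were chosen again when windows 1000 bp away served as controls, where AT-rich words took most places.

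**Figure D3:**
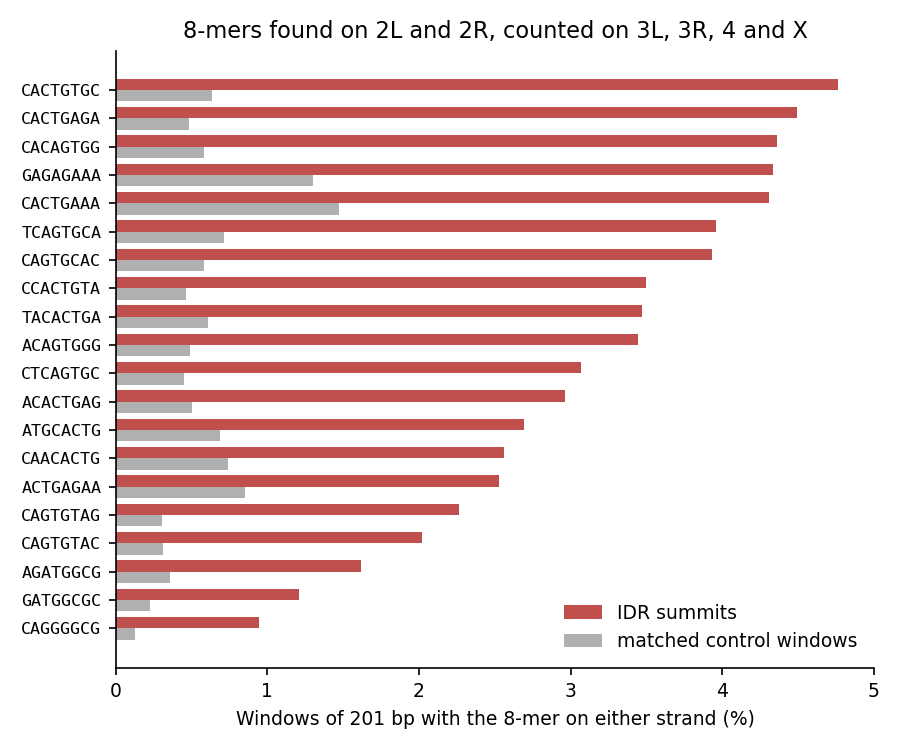
Share of windows reaching 100 bp to either side (percent) that held each of the 20 words on either strand, at the 3714 summits of 3L, 3R, 4 and X (red) and at their 18570 matched control windows (grey). CACTGTGC reached 4.77% against 0.635%, and every word was more frequent at the summits.

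The shared core CACTG was counted afterwards, once the words had been seen. Within 100 bp it was found at 2810 of the 5786 summits (48.6%) and at 24.4% of the matched windows. The words were densest to both sides of the summit, and less dense on it though still above the controls: per 20 bp there were 8.57 per 100 summits at 70 to 90 bp on the left, 8.78 on the right and 4.11 at the summit itself, against 2.67 to 3.53 in the matched windows.

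**Figure D4:**
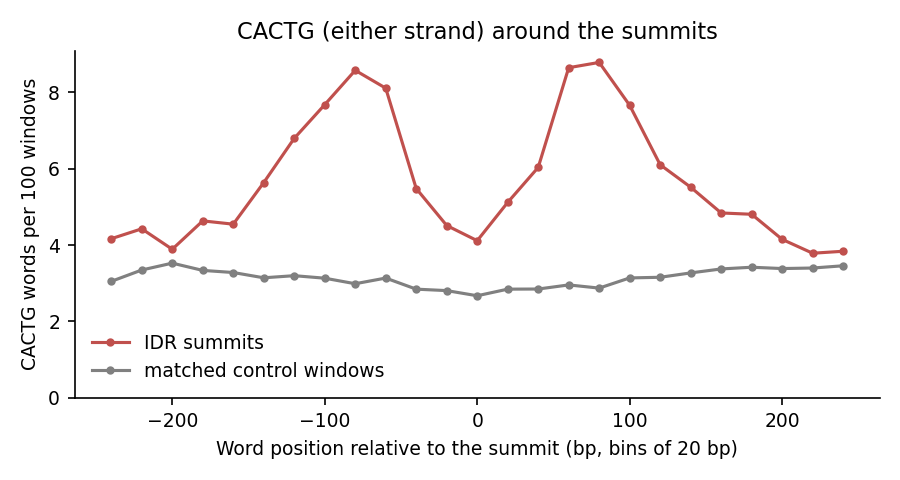
CACTG words on either strand per 100 windows, in 20 bp bins by distance from the summit (bp), for IDR summits and matched control windows. The summits reach 8.57 and 8.78 at 70 to 90 bp on the left and right, with 4.11 in between.

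The older build dm3 gave similar numbers. Its IDR list held 5504 peaks, and the ratio of dm6 to dm3 was 1.05. The relaxed lists of dm3 held 30000, 18755 and 26176 peaks for replicates 1 to 3, and 23697 pooled.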

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

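Of the tests in this part, those of CACTG 50 to 110 bp from the summit and the places of the other motifs and words were chosen only after the profile of words had been seen. The word CACTG was itself read off the 8-mers, so the tests of it use the data it was found in.

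Pooled peaks below the IDR threshold, a set that the tests of genes, motifs and words did not use, also held CACTG more often than their matched windows. The 27145 pooled peaks merge into 23613 regions, so some overlap each other, and those beside an IDR peak were not taken out. Part of the same sequence may thus be counted again. Within 50 bp of the summit the odds ratio was 2.26 (2.02 to 2.53) for pooled peaks ranked 5787 to 10000, 1.72 for ranks 10001 to 15000, 1.36 for ranks 15001 to 20000 and 1.27 for ranks 20001 to 27145. Of the peaks in these 4 ranges of rank below the threshold, 36.2%, 29.0%, 23.7% and 19.0% lay within 500 bp of a TSS. In the 4 classes of IDR peaks, from highest to lowest signal, the odds ratio of CACTG was 1.46, 1.82, 2.13 and 2.13 within 50 bp, and 3.09, 3.00, 2.74 and 2.89 within 100 bp, a window chosen for this word after its profile was seen. In dm3, 38 pooled relaxed peaks lay on heterochromatic or unplaced scaffolds, the best of them at rank 6295 on XHet, and none was in the IDR list.

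CACTG was the core shared by 15 of the 20 words. In the test written beforehand for base composition, its odds ratio within 50 bp of the summit was 1.88 (1.75 to 2.03). That was above the 95th percentile of 59 other words made of the same bases (1.27). The word was picked for its frequency at these summits and would rank high among unpicked words, so this comparison cannot decide on base composition. The 20 words themselves passed on arms not used to choose them, against windows matched for GC class. For those words this argues against GC content of the window as the whole source. The test written beforehand for signal of open chromatin with no fixed site asked whether the word crowds at the summit, and it came out on the side of that explanation: words per bp within 25 bp were 0.553 (0.501 to 0.610) times those 75 to 100 bp away. An even spread around the summit would not give the profile, which had 2.06 (1.93 to 2.19) times as many words per bp 50 to 110 bp away as 200 to 250 bp away; these bounds were picked from that profile, so the value restates it. Fewer words within 30 bp than 50 to 110 bp away was not particular to CACTG (0.558). GAGA (0.310), the DPE motif (0.571), the E-box CACGTG (0.571) and CAGCTG (0.636) also had it. Motif 7 stood at 0.788, but some of its matches hold CACTG. Other motifs had no such dip, among them the DRE (0.993), CGATA (1.06) and Hunchback (0.976). GC content was lowest at the summit (31.8%), and these ratios were not adjusted for its rise to either side. The CTCF core stood at 2.88 (1.72 to 5.09) and the Su(Hw) core at 1.47 (1.12 to 1.93), together at 1.70 (1.35 to 2.16). The Mad and Brinker site (1.87, 1.40 to 2.56) and STAT (1.52, 1.21 to 1.90) were also denser near the summit. GATA (1.19, 1.08 to 1.30) and Homeobox (1.16, 1.04 to 1.32) were slightly so. A higher density near the summit was therefore not particular to insulator motifs. Of the 20 words, only AGATGGCG (3.81, 2.57 to 5.91) and GATGGCGC (2.71, 1.69 to 4.42) were denser within 30 bp than 50 to 110 bp away. It stays open whether az2, other proteins at the same places or chromatin opened between CACTG words may give the pattern of CACTG. No untagged line and no accessibility data were analysed here, and no biological explanation was tested.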

How the results depend on the processing

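The alternatives were set before the data were examined, except 5 added after seeing the data: gene lists without misplaced members, gene lists by promoter region, divergent promoters by the 5'-most TSS, divergent promoters by logistic regression, and motifs with 1 control per summit. Of 72 alternatives to the 9 planned results, 64 left the result on its side of the threshold or within the range set for it. The share of summits near a TSS ranged from 35.2% (250 bp window) to 56.0% (1000 bp window), peaks shared by all 3 replicates from 63.7% to 78.5%, the odds ratio of divergent promoters from 4.36 to 5.08 and that of X from 0.907 to 0.988, and 20 of 20 words passed each time. With the 2893 peaks of higher signal, promoter-bound genes came to 1891, called gene lists to 4 and motifs more frequent at summits to 7, with fewer peaks by construction. Called gene lists were 5 of 27 with logistic regression, which could not be fitted for the 3 lists with 0 bound genes, and 6 to 8 without 1 replicate; by promoter region they were 13. IDR peaks covered in all 3 replicates rose from 72.6% to 96.2% with replicate lists of 2 times the length and to 98.2% with whole lists. Motifs more frequent at summits were 6 within 50 bp, 7 beyond the TSS window and 15 within 200 bp, against 12; the cause was not tested. Calls held in all alternatives for 3 of 11 lists (cytosolic ribosomal proteins, cuticle proteins, chemosensory receptors) and 2 of 18 motifs (Motif 7, CTCF core). Over single lists 258 of 294 values kept their side, 30 lost and 6 gained a call; over single motifs 275 of 352 did, 46 lost and 21 gained one, and 10 turned. The motifs that turned, cause not tested, were GAGA (0.767 within 50 bp, 0.705 against windows 1000 bp away, 0.866 without GC matching), CAGCTG (0.917 against windows 1000 bp away, 0.959 without GC matching), Mad and Brinker (0.753 and 0.991 in the same order), the Su(Hw) core (0.950 near a TSS only), and the DRE (0.602) and BEAF-32 site CGATA (0.898) beyond the TSS window. Of these, only GAGA and Mad and Brinker against windows 1000 bp away passed the test in the other direction. The windows 1000 bp away were not matched for GC content either. Read depth is unknown, so its limit could not be set.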

Other observations

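In this part, the counts per gene body, the count and test of PIG genes, the motifs at ribosomal protein summits, and the values of CACTG within 100 bp or on either side of the summit were chosen only after the results had been seen; the regression of ribosomal protein promoters with covariates was planned, but its use as a test of an explanation was set after its value had been seen, and the other tests of ribosomal protein and divergent promoters were written beforehand.

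The gene bodies with the most summits were picked by their counts, and no group of genes was tested. The gene kirre, for fusion of muscle precursors, held 23 summits over 394 kb of X (5.84 per 100 kb), CG1677 held 18 (14.4 per 100 kb), and the regulators sbb and shn held 14 (17.7 per 100 kb) and 13 (22.3 per 100 kb). Ten-a held 10 over 292 kb (3.43 per 100 kb). The kinase gene Raf held 13 summits (26.9 per 100 kb), ush, a partner of GATA factors, 13 (20.2 per 100 kb), pnt, of EGF receptor signalling, 12 (21.5 per 100 kb), and the forkhead gene CHES-1-like 12 (44.4 per 100 kb). The mean over the genome was 4.32 per 100 kb. The nearest other summit lay a median of 3452 bp away, and within 1000 bp for 22.1% of summits.

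The genes of glycosylphosphatidylinositol anchor synthesis, of which PIG-G and PIG-F stood among the 25 highest promoter peaks, were bound in 11 of 21 cases (52.4%), against 22.6% of protein-coding genes. A test gave an odds ratio of 3.77 (1.45 to 9.91; two-sided Fisher's exact p = 0.0028, not adjusted), but the group was looked at because of those 2 genes, which the test counts, so it is no independent evidence. The bound ones were PIG-A, PIG-C, PIG-F, PIG-G, PIG-K, PIG-L, PIG-M, PIG-Q, PIG-S, PIG-U and PIG-Z.

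The core word CACTG was frequent at distal summits as well as at promoters. Within 100 bp it was found at 52.2% of summits beyond 500 bp from a TSS (22.2% of matched windows; odds ratio 3.83, 3.54 to 4.16) and at 44.2% of those within (27.0%; 2.15, 1.97 to 2.34); the difference between them was not tested. Within 50 bp the distal odds ratio was 2.06 (1.86 to 2.27), in a test written beforehand on whether the word belongs to promoters in general. A word stood 50 to 110 bp to the left of 1287 summits, to the right of 1337 and on both sides of 421, against 297 expected if sides were independent (odds ratio 1.90, 1.65 to 2.19; two-sided Fisher's exact p = 2.04e-19). Words on both sides were not counted in matched windows. Summits that differ in how often they hold the word would also give such an excess, so it does not show that words are paired. GC content rose from 31.8% at the summit to 43.7% at 250 bp. Words of the same bases had a 95th percentile of 1.22 for the ratio of 50 to 110 bp over 200 to 250 bp. Within 20 kb of az2 there were 16 relaxed pooled peaks, at the 88.5th percentile of 10000 places on 2R, where the 95th percentile was 19 peaks. The high PIG-G peak lay in this stretch, and a count of peaks does not weigh their signal. The count therefore cannot decide whether the tagged copy of az2 adds to the signal at az2 or PIG-G.

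Binding at cytosolic ribosomal protein promoters was not due to shared promoters alone, since among genes with no other TSS within 500 bp the odds ratio was 7.94 (4.05 to 15.8). With the number of TSSs, their spacing and GC content as covariates it was 6.12 (3.82 to 9.81). Whether these peaks are enrichment at active promoters without a fixed site stays open: CACTG within 50 bp of their summits had an odds ratio of 1.63 (0.817 to 3.13) over matched windows, with too few summits to decide. Within 100 bp it was 43.1% against 27.1% (odds ratio 2.03, 1.13 to 3.64), and of 32 motifs counted at these 65 summits the DRE (odds ratio 6.16), the BEAF-32 site CGATA (3.15) and Motif 7 (2.88) were more frequent than in matched windows and the Initiator (0.265) less. The DRE palindrome holds CGATA, so their counts overlap. The matched windows came from unbound TSSs of any gene, and unbound ribosomal protein promoters were not compared. These motifs may therefore describe ribosomal protein promoters in general. Gene activity and the background of an untagged line were not analysed here and stay open, and no biological explanation was tested.

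Divergent promoters offer a wider stretch in which a summit can fall, but the length of that stretch alone does not account for their higher share. With 1 gene per pair and only summits 0 to 250 bp upstream, 630 of 2110 (29.9%) against 664 of 9320 (7.12%) were bound. The odds ratio was 5.55 (4.90 to 6.28). Those 250 bp can still take in the TSS of the partner, so the test does not remove the added chance from a second promoter. Without the 502 listed housekeeping genes the odds ratio over all divergent genes was 4.51 (4.12 to 4.93), so those lists are not the whole source. Chromatin that is more open at divergent promoters was not measured and stays open, and no biological explanation was tested.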
